A study of Mus musculus and unidentified plasmid with 60 samples.

How the data were processed

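The series holds 60 mouse samples, of which 8 are ChIP-seq libraries in 4 groups of 2. The other 52 samples are reporter RNA, plasmid DNA and barcode key libraries and were not analysed here. Processed lists of bound regions were used for 3 of the ChIP-seq groups. These are neurons with the dominant-negative RFX construct at 0 h of depolarization, the same at 1 h, and a group titled WT. The 2 input libraries were not used here. No read-level data were used, so the depth of the libraries is unknown.

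Each list was deposited once for its 2 libraries, as combined regions with a chromosome number, a start and an end. The chromosomes run from 1 to 21 in the lists' own numbering, in which 20 and 21 presumably stand for X and Y. Per the file headers, 2 further columns named c1 and c2 accompany each region. From the values, each of these columns holds a position inside the region or a mark that there is none, and no region lacks a position in both. They were read as the peak centre in each of 2 replicates. The columns do not say which library is which, so the first column of one list was not taken to match the first column of another. Per the submitters' processing notes, Bowtie and the mouse build mm9 were used. The peak caller, its threshold and the way in which the replicates were combined are not given in the sources used here. Starts and ends are printed as the lists give them, in mm9, and whether they count from 0 or 1 is not given in the sources used here.

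Regions were counted as shared when they overlapped by at least 1 base. The overlap expected at random positions came from 1000 circular shifts of the query list within the span of each chromosome, with seed 1. It is not the overlap to expect between 2 unrelated ChIP-seq lists. Shift p-values are one-sided and cannot go below 0.001. Such a shift test asks only whether 2 lists overlap more than at random positions, and regions are not replicates. Where overlap of at least 50% of both regions was required, the shifts still counted overlap by 1 base, which makes the expected value an upper bound. Centres in different columns were counted as shared within 250 bases. Numbers of centres per column were compared between 0 h and 1 h with a two-sided exact permutation test. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so its p-value measures the spread between these libraries, which may be technical. Confidence intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Local clustering of unshared regions was tested with 1000 permutations of the shared and unshared labels within strata of column support and 10 width classes. Its 4 p-values were adjusted by the Benjamini-Hochberg method. The test was repeated on pairs with centres of both columns and after merging 1 h regions within 500 bases of one another, without adjustment.

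The counts of regions, the overlaps between lists with their shift tests and the rule for naming regions were fixed before the data were examined. The permutation test of centres per column, the Fisher's exact tests, the clustering tests and the counts of both-column regions absent from the other list were chosen afterwards. The rule takes all WT regions up to 15 and otherwise 10 of them, 10 regions of each RFX-DN list, 5 regions of the 0 h list absent at 1 h and 5 of the 1 h list absent at 0 h. It orders regions by the authors' score and, where a list has none, by width. The lists hold no score, so width was used, and ties were taken in order of position. The rule's gene list members could not be named. No gene assignment comes with the lists and no mm9 genome or annotation was used, so region-to-gene assignment, the promoter share, the tests of 16 fixed gene lists and the motif tests were not run. Tests of the authors' scores were not run either, and widths of shared and unshared regions are described in their place.

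The overlap and shift code was tested on simulated lists. In lists of 40000 regions drawn from the 0 h list, the planted shares of overlap were recovered with an error of 0 percentage points. The planted regions were exact copies, and the same overlap code kept the others clear of the list. An error of 0 therefore follows from how the lists were built, and partial overlaps were not simulated. Of 20 simulated lists of 3000 regions placed uniformly at random within each chromosome and set against the 0 h list, 0 had a shift p of 0.05 or less. Unrelated lists whose regions cluster were not simulated. The clustering test was run on 20 random label sets of 8000 regions on the 1 h list, of which 0 had a p of 0.05 or less, either for all pairs or for pairs with centres of both columns. After 60 runs of 3 neighbouring regions were planted in each of 5 such sets, all 5 had a p of 0.05 or less. The data held only 7 windows of 10 kb with at least 3 1 h-only regions, so detection of clustering as weak as that observed was not tested. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives comprised stricter overlap, centre distance, removal of chromosome 21, width-based selections, regions in both columns, and omission of each column in turn.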

Results

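Regions bound by a dominant-negative RFX protein were mapped by ChIP-seq in cortical neurons of E16 CD-1 mouse embryos. RFX proteins are transcription factors that bind X-box sequences. A dominant-negative form interferes with the function of the native proteins. The construct was delivered by lentivirus on day in vitro (DIV) 2, and the chromatin was precipitated with an antibody against the MYC tag. Neurons were silenced overnight from DIV 6 with tetrodotoxin and an NMDA receptor antagonist. On DIV 7 they were depolarized with 55 mM KCl, a standard way to mimic strong neuronal activity, for 0 or 1 h. Another group, titled WT, carries no treatment in its labels. Whether its neurons carried the construct is unclear, since the protocol text shared by all ChIP-seq samples describes transduction and the description of its list contains the construct's abbreviation. Each list combines 2 libraries, and each of its regions carries a centre in 1 or both of 2 replicate columns.

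The first comparison asked how binding of the construct differed between silenced neurons and neurons depolarized for 1 h. The list from silenced neurons held 173231 regions covering 38.8 Mb, and the list after 1 h held 122135 regions covering 27.5 Mb. The WT list held 43 regions. Median widths were 200 bases at 0 h (quartiles 120 and 300), 210 bases at 1 h (quartiles 130 and 300) and 200 bases in WT. Each replicate column held 139437 ± 23368 centres at 0 h and 94522 ± 28477 at 1 h (mean ± SD, n = 2 columns). The ratio of these means was 1.48. Both 0 h columns, with 155961 and 122913 centres, exceeded both 1 h columns, with 114659 and 74386. With 2 columns against 2, the two-sided exact permutation p was 0.333, which is the smallest this design allows, so the difference could not pass a threshold of 0.05.

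**Figure D1:**
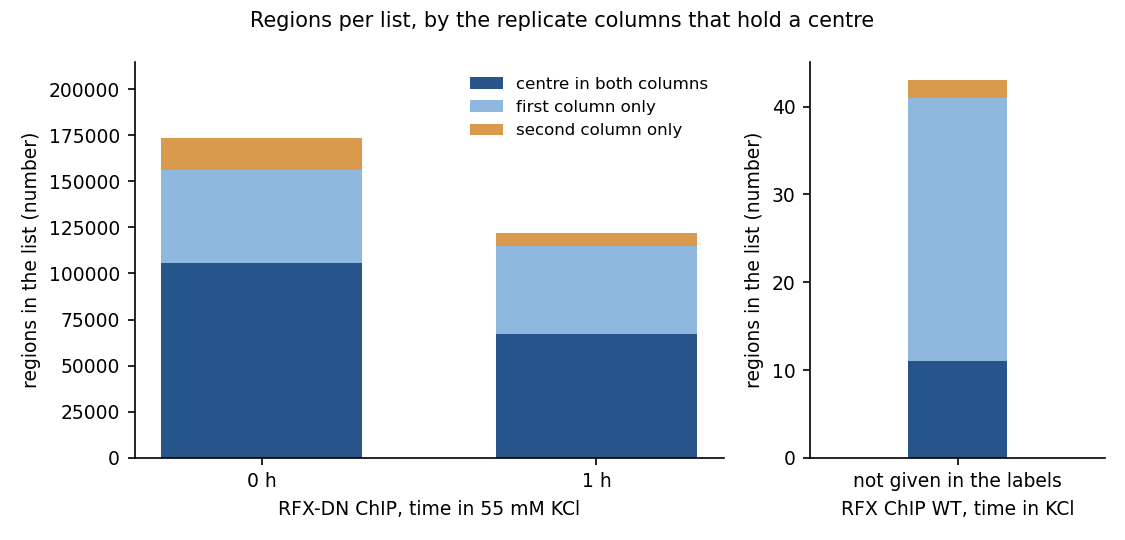
Stacked bars give the number of regions per list on a linear axis, with the RFX-DN lists on the left and the WT list on its own scale on the right. Colours show whether both replicate columns or 1 of them held a centre, with both columns holding one in 105643 regions at 0 h, 66910 at 1 h and 11 in WT.

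The widest regions were listed at both times. The widest region of both lists lay on chromosome 13 (mm9), from 20006890 to 20013810 at 0 h and from 20006900 to 20013780 at 1 h. The region next in width in both lists lay on chromosome 9, from 72464340 to 72467800 at 0 h and from 72464460 to 72467700 at 1 h, and the WT list held a region there too. Chromosome 12 (117814590 to 117816760 at 0 h) and chromosome 5 (124798190 to 124800170 at 0 h) also gave regions among the 10 widest of both lists, with widths of 2170 and 1980 bases at 0 h and of 2040 and 1960 bases at 1 h. All 10 of the widest 0 h regions overlapped a 1 h region and all 10 of the widest 1 h regions overlapped a 0 h region, while 4 of the 10 stood in both sets.

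All 10 of the widest 0 h regions had a narrower counterpart at 1 h, by little for those in both sets and by more for the other 6. Chromosome 17 held a region of 3450 bases at 0 h (12816190 to 12819640) whose 1 h counterpart was 1380 bases wide, and another of 2690 bases (56243750 to 56246440) whose counterpart was 450 bases wide. The region on chromosome 18 from 82695300 to 82697430 was 2130 bases wide at 0 h and 930 bases at 1 h. Regions on chromosome 12 (88142140 to 88144150), chromosome 15 (13727240 to 13729230) and chromosome 1 (120599670 to 120601580) had widths of 2010, 1990 and 1910 bases at 0 h and 1060, 950 and 860 bases at 1 h. Among the 10 widest at 1 h only, the region on chromosome 4 from 108672700 to 108674500 was 1800 bases wide at 1 h and 860 bases at 0 h. The others were of similar width at 0 h. They lay on chromosome 1 (183282200 to 183284230 and 73051230 to 73052940), chromosome 5 (134789400 to 134791260), chromosome 17 (3083090 to 3084890) and chromosome 2 (109512960 to 109514620), with 1 h widths of 2030, 1710, 1860, 1800 and 1660 bases and 0 h widths of 1770, 1770, 1860, 1810 and 1700 bases. A combined region's width has no replicate error, and no test was made of these differences. Choosing the widest regions of 1 list in itself favours narrower counterparts in the other. Some 0 h regions also met more than 1 region at 1 h, since 113965 regions at 1 h met 113274 at 0 h. Only 1 counterpart width is given for each, so a region listed in pieces may look narrowed.

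Nearly every region bound after 1 h of depolarization had also been listed in silenced neurons. Of the 122135 regions at 1 h, 113965 (93.3%) overlapped a 0 h region, against 3.10% in circular shifts (highest shift 3.35%, permutation p = 0.001, the smallest the 1000 shifts can give). Of the 173231 regions at 0 h, 113274 (65.4%) overlapped a 1 h region, against 2.18% in shifts (permutation p = 0.001, again the smallest). Shared regions were wider than unshared ones, with medians of 260 and 100 bases at 0 h and of 220 and 70 bases at 1 h.

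Sharing followed the support by the replicate columns. A centre in both columns was held by 61.0% of 0 h regions and 54.8% of 1 h regions, and the paired centres lay a median of 10 bases apart in either list. Among 0 h regions, 84.9% of those with centres in both columns overlapped a 1 h region, against 41.3% of those with a centre in the first column only and 15.9% of those with a centre in the second only. Among 1 h regions the shares overlapping a 0 h region were 99.6%, 86.1% and 83.1%. Between the columns of 1 condition, 67.5% of first-column centres at 0 h had a second-column centre within 250 bases, and 85.7% the other way round. At 1 h these shares were 58.2% and 89.6%. Between conditions, 92.0% of first-column and 94.5% of second-column centres at 1 h had a first-column centre at 0 h, and 75.4% and 93.8% a second-column centre. In the other direction, 67.6% of first-column and 70.3% of second-column centres at 0 h had a first-column centre at 1 h, and 45.1% and 56.8% a second-column centre. These shares depend on the number of centres in the column searched, from 74386 to 155961, so they do not rank agreement within against between conditions.

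**Figure D2:**
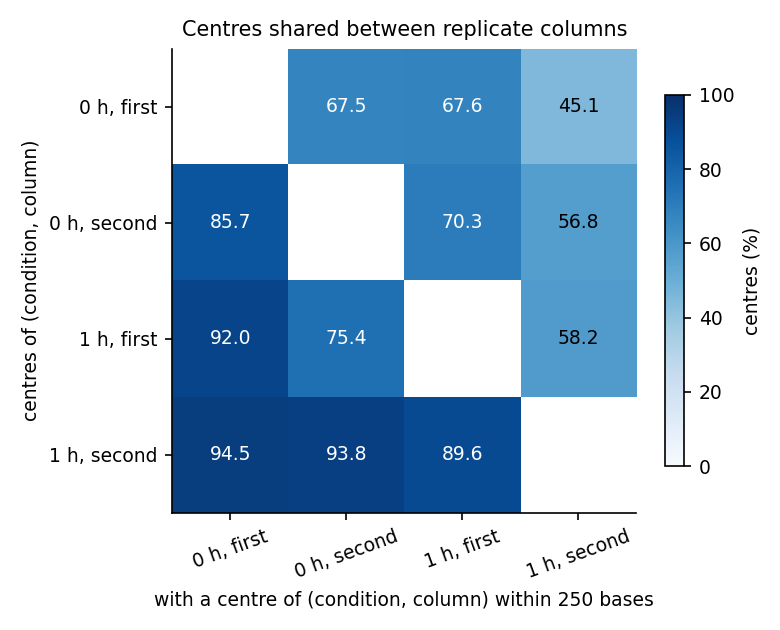
Each cell gives the percentage of centres of the replicate column named on the vertical axis that had a centre of the column named on the horizontal axis within 250 bases. The second 1 h column, which held the fewest centres, was found at 94.5% and 93.8% in the 0 h columns and at 89.6% in the other 1 h column, shares that also depend on how many centres the searched column held.

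Regions with centres in both columns at 0 h and no counterpart at 1 h numbered 15919, or 15.1% of such 0 h regions, with a median width of 170 bases. The reverse set, with centres in both columns at 1 h and no counterpart at 0 h, numbered 291, or 0.435%, with a median width of 150 bases. Both counts depended on the overlap required: with at least 50% of both regions they were 27956 and 4438 (6.63%), and with centres within 250 bases 16647 and 1068 (1.60%). Leaving the first 1 h column out raised the former count to 36876. Leaving the first or the second 0 h column out raised the latter to 1819 or 743. Retention was lowest among narrow regions. Of the 0 h regions with centres in both columns, divided by width into 5 classes of equal size, 50.2% of the narrowest class were found at 1 h and 98.2% of the widest.

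**Figure D3:**
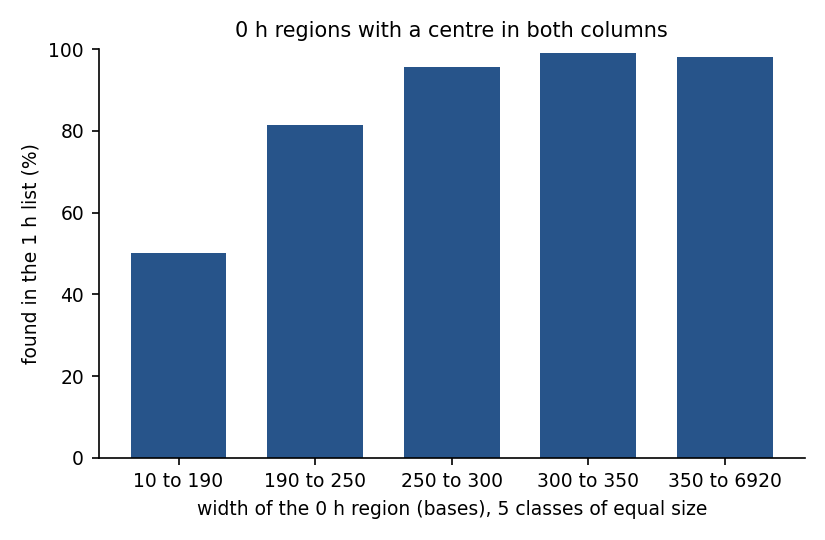
Bars give the percentage of 0 h regions with centres in both columns that overlapped a 1 h region, in 5 classes of equal size by width in bases. The shares were 50.2%, 81.5%, 95.7%, 99.1% and 98.2% from the narrowest to the widest class.

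The 5 widest 0 h regions absent at 1 h had centres in both columns. They lay on chromosome 12 (83422260 to 83423160, 900 bases, and 47808680 to 47809570, 890 bases), chromosome 11 (85583560 to 85584420, 860 bases), chromosome 14 (24846920 to 24847770, 850 bases) and chromosome 13 (24291140 to 24291980, 840 bases). Of the 5 widest 1 h regions absent at 0 h, 3 had centres in both columns. These were on chromosome 7 (52380150 to 52380690, 540 bases), chromosome 15 (80089230 to 80089760, 530 bases) and chromosome 8 (73227050 to 73227520, 470 bases). The regions on chromosome 20 (130819810 to 130820460, 650 bases) and chromosome 4 (48066620 to 48067130, 510 bases) had a centre in the first column only.

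The window of 10 kb with the most regions listed only after depolarization was on chromosome 12, in an interval chosen after its values were seen. Between 86814510 and 86819170, a span of 4.66 kb, the 1 h list held 5 regions with no counterpart at 0 h. Of these, 1 had centres in both columns, 3 in the first only and 1 in the second only. They ran from 86814510 to 86814650, 86814670 to 86814700, 86815890 to 86815910, 86817100 to 86817320 and 86819160 to 86819170. The leftmost and its neighbour nearly touched and may be 1 site, and the rightmost had the list's minimum width of 10 bases. An interval on chromosome 15, also chosen after its values were seen, held 4 such regions between 101100210 and 101103960, of which 1 had centres in both columns.

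**Figure D4:**
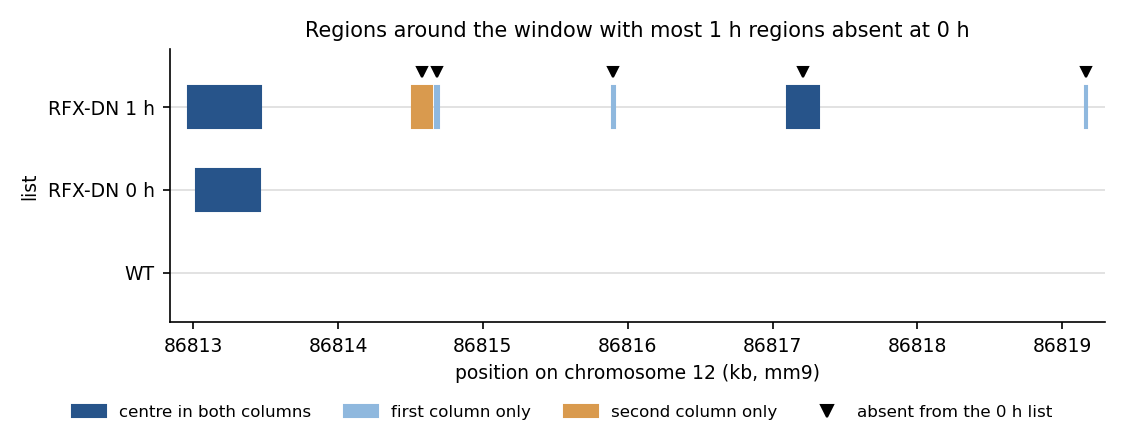
Boxes mark the regions of each list to scale along chromosome 12 in kb (mm9), coloured by the replicate columns that held a centre, and triangles mark 1 h regions absent at 0 h. The 5 marked regions are spread over 4.66 kb, of which the leftmost and its neighbour nearly touch, while the only 0 h region shown, at the left, is shared.

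The second comparison set the RFX-DN lists against the WT list. Of the 43 WT regions, 33 (76.7%, 95% exact Clopper-Pearson interval 61.4% to 88.2%) overlapped a 0 h region and 36 (83.7%, interval 69.3% to 93.2%) a 1 h region. Circular shifts gave means of 1.52 and 1.07 regions (permutation p = 0.001 for both, the smallest the shifts can give). All 33 that met the 0 h list also met the 1 h list, and 7 met neither. The regions that met WT made up 0.0190% of the 0 h list and 0.0295% of the 1 h list. A centre was held by 41 WT regions in the first column and by 13 in the second, with 11 holding both. When the first WT column was left out, 13 regions remained, and all 13 met both lists. With only RFX-DN regions that had centres in both columns, 15 WT regions met the 0 h list and 11 the 1 h list, and without the first 1 h column 20 met the 1 h list.

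The widest WT region lay on chromosome 9 (72464510 to 72467570, 3060 bases) and had centres in both columns. Centres in both columns were also held by regions on chromosome 19 (27880650 to 27881350, 700 bases), chromosome 17 (4626060 to 4626700, 640 bases) and chromosome 6 (10136260 to 10136600, 340 bases). The remaining 6 of the 10 named had a first-column centre only. They lay on chromosome 17 (56339290 to 56339650), chromosome 1 (12634720 to 12635070 and 45007930 to 45008270), chromosome 10 (79371620 to 79371970), chromosome 2 (60240690 to 60241030) and chromosome 6 (125826790 to 125827130), with widths of 340 to 360 bases. All 10 met both RFX-DN lists.

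A run of 11 WT regions, chosen after its values were seen, lay within 81.55 kb of chromosome 19, from 27842980 to 27924530. In the WT list itself, 9 of the 11 had a first-column centre, 8 a second-column centre and 6 both. All 11 met both RFX-DN lists. At 0 h all 11 counterparts had a second-column centre and 3 had a first-column centre, whereas all 22 counterparts of the other WT regions had a first-column centre (two-sided Fisher's exact test p = 1.19e-05). At 1 h the numbers were 2 of 11 and 25 of 25 (two-sided Fisher's exact test p = 5.84e-07). These tests treat neighbouring regions as independent and were chosen after the pattern was seen. Within the same span the RFX-DN lists held 4 regions each that did not meet WT, and all 4 had a first-column centre in either list.

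**Figure D5:**
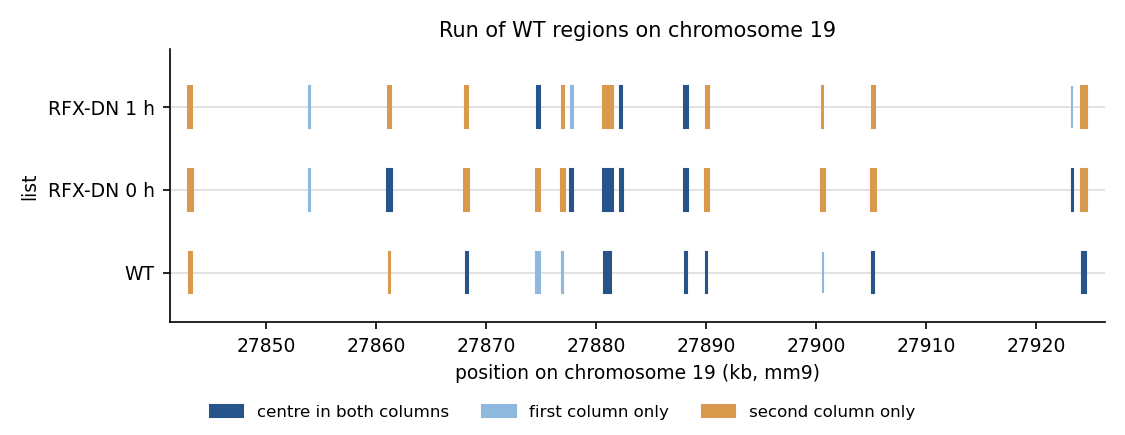
Boxes mark the regions of each list to scale along chromosome 19 in kb (mm9), coloured by the replicate columns that held a centre. The 11 WT regions each have a counterpart at 0 h and at 1 h, and 8 counterparts at 0 h and 9 at 1 h were held by the second column only.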

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

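Alternatives built on widths, on regions in both columns or on leaving out a replicate column were chosen after seeing the data, as were all those for the regions absent from the other list. No paired analysis was possible because the 2 columns of a list name no library. Matched by column name alone, 0 h exceeded 1 h by 41302 and 48527 centres, and 2 pairs allow no two-sided exact p below 0.5. Alternatives based on the authors' scores, on transcription start sites, on genes and on motifs were not run, since the lists hold no scores and no mm9 annotation or genome was used. The share of 1 h regions met at 0 h stayed above that of the shifts under all 10 alternatives (permutation p = 0.001 in each, the smallest possible), from 76.4% without the first 0 h column to 97.9% without the first 1 h column. Merging overlapping or touching regions changed no list's count. Restriction to regions with centres in both columns left 105643 regions at 0 h, 66910 at 1 h and 11 in WT, each list taken alone. With all 43 WT regions set against the RFX-DN lists so restricted, 15 met the 0 h list and 11 the 1 h list. This kept 45.5% and 30.6% of the WT regions met, against 61.0% and 54.8% of the regions in the lists, and the cause was not tested. Without 1 replicate column, the 1 h list held 74386 to 114659 regions (lowest without the first) and the WT list 13 to 41 (lowest without the first). WT regions met numbered 13 to 31 at 0 h and 13 to 34 at 1 h with 1 column left out, in both cases lowest without the first WT column, and 20 at 1 h without the first 1 h column. Requiring overlap of at least 50% of both regions raised the both-column regions absent from the other list to 27956 for 0 h and 4438 for 1 h. With centres within 250 bases, the 1 h count was 1068. Without 1 column of the other list, the counts were 19865 to 36876 for 0 h and 743 to 1819 for 1 h, as follows from a shorter list to meet. The 0 h excess over 1 h held under each of these. The ratio of mean centres per column was 1.22 to 1.87 with 1 column left out. Depth is unknown, so no limit of detection could be given.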

Other observations

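All tests reported here were chosen after the pattern they bear on was seen, and for calls of a single library and for split sites the criterion was set before the test was run. Chromosome 20 in the lists' numbering, presumably X, had few listed regions per Mb. It held 27.8 regions per Mb at 0 h and 20.2 at 1 h, against 70.4 ± 5.90 and 49.6 ± 4.31 on chromosomes 1 to 19 (mean ± SD over 19 chromosomes). The lowest of those were 61.3 on chromosome 3 at 0 h and 43.4 on chromosome 14 at 1 h. Relative to chromosomes 1 to 19, the density of centres on chromosome 20 was 0.373 ± 0.0365 (SD, n = 4 columns). For regions with centres in both columns it was 0.341 at 0 h and 0.328 at 1 h. Counting only windows of 100 kb with a region in either list gave 0.455 and 0.470. Centres in both columns were held by 52.5% of its 0 h regions, against 61.2% ± 1.53 on chromosomes 1 to 19. Retention of 0 h regions at 1 h was 65.2% on chromosome 20 and 65.4% ± 0.776 on the others. In the other direction, 89.9% of its 1 h regions were found at 0 h, against 93.4% ± 0.490 on the others, whose lowest was 92.4%. Whether less binding or weaker detection accounts for the low density on chromosome 20 was not tested.

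Regions were most crowded on chromosome 5 between 112100000 and 112200000, with 31 regions at 0 h and 22 at 1 h, against a median of 6 and 5 in windows of 100 kb that held any. At 1 h the most crowded window was on chromosome 6, from 114400000 to 114500000, with 25 regions, where the 0 h list held 27.

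The 1 h list was shorter than the 0 h list and almost contained in it. With both lists cut to the same number of widest regions, 83.8% of 1 h regions were met at 0 h, against 93.3% in the full lists. The containment thus rests in part on the longer 0 h list. A difference in detection alone, such as in sequencing depth or in the fraction of precipitated DNA, would leave few strong regions at 1 h without a 0 h counterpart. Of the 1 h regions with centres in both columns, 0.435% were absent at 0 h by overlap of 1 base, 1.60% by centres within 250 bases and 0.381% by distance within 500 bases, as this explanation needs, while overlap of 50% of both regions, which also counts changes of extent, failed for 6.63%. Regions missed at 1 h were mostly narrow, yet 384 of the widest class were missed against 188 of the class below it. Loss of binding after depolarization also stays open, since a general loss would leave a contained list too and the exact permutation p of 0.333 is the smallest that 2 columns per condition allow.

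With the shared and unshared labels permuted within classes of support and width, 222 pairs of 1 h-only regions in the same window of 10 kb compared with a mean of 170 (highest 212, adjusted permutation p = 0.00133 over 4 tests), which argues against random scatter. At 100 kb the 1577 pairs were close to the mean of 1575 (adjusted permutation p = 0.467), although 3 windows held at least 6 such regions against a mean of 0.13, and 7 windows of 10 kb held at least 3 against 2.67 (unadjusted permutation p = 0.001 and 0.0140). The fullest window of 100 kb held 6, the cut used there, against up to 7 in the permutations (unadjusted permutation p = 0.128). At 10 kb the fullest held 5, against up to 4 (unadjusted permutation p = 0.001). The 0 h regions absent at 1 h also exceeded chance in pairs, with 9321 against a mean of 9115 at 10 kb and 89192 against 86685 at 100 kb (adjusted permutation p = 0.00133 for both). Their windows of 10 kb with at least 3 regions did not, at 838 against a mean of 808 (unadjusted permutation p = 0.0769). Windows of 100 kb with at least 6 did, at 1913 against 1757 (unadjusted permutation p = 0.001). As the whole cause, calls of a single library are argued against by the 112 of the 222 pairs that held centres of both columns. The mean in the permutations was 73.4 (highest 97, permutation p = 0.00100, the smallest possible). Sites split into regions within 500 bases of one another are argued against, as the whole cause, by the pairs left after such 1 h regions were merged. These numbered 168, against a mean of 134 (permutation p = 0.00200). Pieces of a broad interval that lie further apart than 500 bases would not be merged, so that form of splitting stays open. Binding gained at loci that respond to depolarization is a hypothesis that remains open, as no gene was assigned. The permutations show only that such regions lie close together, so they neither favour this hypothesis nor exclude causes not tested here.

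For the run of WT regions on chromosome 19, a mapping artefact common to every library is argued against by the counterparts without a first-column centre, 8 of 11 at 0 h and 9 of 11 at 1 h. The Fisher's exact tests at 0 h of first-column centres (two-sided p = 1.19e-05) and of second-column-only regions against the rest of the list (two-sided p = 1.22e-06) treat neighbouring regions as independent and restate the pattern that prompted them, so they add nothing to these counts. DNA copied from a coding sequence, such as that of an expression construct, is a candidate explanation, because it would give a series of short regions over the exons of 1 gene in those libraries that carry it. The construct was delivered for both the 0 h and the 1 h lists. Its DNA in every RFX-DN library would not account for the few first-column centres there, 3 of 11 at 0 h and 2 of 11 at 1 h, against 9 of 11 in WT. No test bears on this candidate. It stays open, as exon positions in mm9 and the sequence of the construct were not used here. Binding in the WT neurons, biological in origin, was not tested either.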
